A study of Mus musculus with 10 samples.

How the data were processed

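Array comparative genomic hybridisation was analysed for 10 mouse BCR-ABL1 leukemias, 5 of them Ikzf1+/+ and 5 Ikzf1+/-. Per the labels, DNA of GFP-positive leukemic bone marrow cells was extracted with phenol and chloroform, 1.5 µg was labelled with a ULS kit, and leukemic DNA carried Cy5 while stage-matched non-leukemic bone marrow DNA carried Cy3. The design text of the series names the normal DNA as that of B220-positive B cells. No array had the dyes swapped, so a dye effect shared by all arrays stayed in every ratio. Groups and replicate numbers were taken from the labels.

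Each deposited scanner file gave a spot's Cy5 and Cy3 intensity as the scanner software's processed signal, which that software subtracts for background and normalises between dyes; per the file headers the protocol was one for CGH whose name states lowess, and its single parameters were not used here. The submitters' processing notes name Agilent Feature Extraction 10.5.1.1, and the file headers give version 10.7.3.1 and the genome build mm9. The deposited series matrix held log2 ratios, whose scale and direction were settled by comparison with the scanner's own log10 ratio of Cy5 over Cy3 on each array. With the scanner's ratio converted from log10 to log2, the regression slope of the matrix values on it was 1.00 on every array and the intercept near 0, so the columns had not been centred. Their medians were -0.010, -0.010, -0.019, -0.011 and -0.014 in Ikzf1+/+ tumours 1 to 5 and -0.0011, -0.0011, -0.00060, -0.0019 and -0.0030 in Ikzf1+/- tumours 1 to 5.

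From these files, log2 of processed Cy5 over processed Cy3 was computed for each of 412783 spots that were not controls. Spots marked as non-uniform or population outliers were left out, spots of one probe were averaged, and each array was centred on its autosomal median. Of 402404 probes, 402346 had a chromosome position, with 382487 on autosomes, 19253 on X and 606 on Y, and the other 58 were left out. Probes lay 5.34 kb apart in the median on autosomes, and 392597 were well above background and unsaturated in both channels on all 10 arrays. The number of arrays limits the precision of each group mean.

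Each array was segmented on its own with penalised least-squares change points (PELT, written for this work, with numpy 2.4.6 and numba 0.67.0 under Python 3.11.15), with at least 3 probes per segment and a penalty of 2 times the noise variance times the natural logarithm of the probe number. Single probes were limited to 4 noise SDs around a running median of 11 probes before change points were sought. A called segment had at least 5 probes and an absolute mean log2 ratio of at least 0.3. Called segments of one direction were joined, with the DNA between them, where the segments between had under 5 probes or lay at 0.15 or more in that direction, so the mean of a joined call can lie below 0.3. Joining was not part of the design fixed before the data were examined, and the values without it are given beside the results. Calls overlapped by calls of 8 or more arrays over at least 50% of their length were counted apart. This rule takes out a short call and keeps a longer one at the same place. Tested on simulated data, 20 events of each kind on the autosomal probes, the procedure recovered 75% of 5-probe losses of -0.8 at the noise of Ikzf1+/+ tumour 1 and 100% at that of Ikzf1+/- tumour 3. At these noise levels it recovered 0% and 0% of 5-probe losses of -0.4, 0% and 5% of 5-probe gains of 0.4, 10% and 90% of 10-probe losses and 15% and 75% of 10-probe gains of that size. Of 20-probe losses it recovered 85% and 100%, of 20-probe gains 80% and 100%, and of 50-probe events 100%, with 0 false calls. The simulated noise was drawn independently for each probe, without waves along the genome. The 0 false calls therefore do not describe arrays with such waves.

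Values per tumour were compared with two-sided exact permutation tests of the difference in means (pandas 2.3.3, scipy 1.17.1), for which 5 against 5 arrays give 252 splits and a smallest p of 0.00794. Benjamini-Hochberg adjustment was made over 4 call measures, over 19 autosomes, or over all windows. Windows of 100 kb with at least 3 autosomal probes, 23425 with a median of 14 probes, were tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes on the mean over probes) at an adjusted p of 0.05. Simulated differences between the genotypes in 50 of these windows each were recovered in 34%, 96%, 100% and 100% of cases at 0.15, 0.3, 0.5 and 1 on the log2 scale, with 8 false calls. Runs of 5 consecutive probes on chromosome 11 were tested the same way. Fisher's exact test, two-sided, compared the number of tumours with a call in each window. Plots were drawn with matplotlib 3.10.9.

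Gene positions in mm9 were not used here, and the gene table at hand is of GRCm38, so no probe, window or segment was assigned to a gene. The table served only to name the chromosome of each gene of 5 lists, in which 108 of 108 genes were matched; 1 list result is not reported here. Windows therefore stood for genes, all chromosome 11 runs for Ikzf1, and a chromosome 12 region defined from the calls for the antigen receptor loci, substitutions made after the files had been seen. The gene-level Ikzf1 value, the receptor locus windows, the test of list genes lost per tumour and a GC correction were not run. Before the data were examined it was fixed that the text names, per limma contrast and direction, the 10 windows of largest difference past the threshold with at most 1 per Mb, and the 10 losses and 10 gains called in most tumours. The same rule was applied to the chromosome 11 runs.

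Alternatives were normexp background correction (limma, offset 50) on median spot and background signals, since mean spot signals, which had been planned, were not used here; loess within arrays; the deposited series matrix; bright unsaturated probes; other probe minimums (3 and 10), call thresholds (0.2 and 0.5) and penalties (4); medians over probes; robust eBayes; X and Y included; slide as a random block; replicate number as a block; and each tumour left out in turn. The normexp ratios had no normalisation between dyes other than centring each array on its autosomal median. The 5 slides held 2 arrays each, and 1 slide held both genotypes, with Ikzf1+/+ tumour 5 and Ikzf1+/- tumour 1. X and Y were left out of all calls and windows and are given as medians.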

Results

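Genomes of 10 mouse leukemias driven by BCR-ABL1, a fusion tyrosine kinase, were compared with non-leukemic bone marrow DNA on arrays of 402346 placed probes. The tumours were 5 Ikzf1+/+ and 5 Ikzf1+/-, Ikzf1 being the gene of the lymphoid transcription factor Ikaros. A ratio above 0 meant more DNA in the tumour. The median background-subtracted Cy5 signal of tumour DNA was 120 ± 33.4 in Ikzf1+/+ and 216 ± 9.93 in Ikzf1+/- arrays (SD, n = 5 each, two-sided exact permutation p = 0.00794), and that of the Cy3 reference was 174 ± 5.76 and 160 ± 8.12 (exact p = 0.0238). Probe noise was 0.206 ± 0.0145 and 0.180 ± 0.00969 as an SD of log2 ratios (n = 5 each, exact permutation p = 0.0238). The labels did not state whether tumours of one genotype came from separate animals, so the p-values measure the spread between these samples.

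Chromosome 11, which carries Ikzf1, was examined first to check the genotype labels. Of 4763 runs of 5 consecutive probes, 33 differed between genotypes in limma after Benjamini-Hochberg adjustment, 8 higher and 25 lower in Ikzf1+/- tumours. The run from 98499020 to 98502081 lay at -0.52 ± 0.06 in Ikzf1+/+ and +0.13 ± 0.10 in Ikzf1+/- tumours (SD, n = 5 each, limma adjusted p = 1.23e-06), and that from 121783963 to 121841954, near the distal end of the chromosome, at -0.30 ± 0.06 and +0.26 ± 0.08 (limma adjusted p = 3.71e-06). The run from 116403422 to 116422113 lay at +0.06 ± 0.08 and +0.64 ± 0.18 (limma adjusted p = 0.000282). Among runs lower in Ikzf1+/- tumours, the largest difference was at 50106588 to 50130811, with +0.66 ± 0.28 in Ikzf1+/+ and +0.06 ± 0.04 in Ikzf1+/- (limma adjusted p = 0.00405). At 116609271 to 116616804 the means were +0.03 ± 0.16 and -0.55 ± 0.25 (limma adjusted p = 0.00715). The other named runs higher in Ikzf1+/- tumours started at 110925444, 12899957 and 36981974, with differences from +0.21 to +0.25. The other named runs lower in Ikzf1+/- tumours started at 79056930, 60761784, 51416360, 75114277, 44785008, 69402507, 118045638 and 120423756, with differences from -0.54 to -0.30. On the slide that held both genotypes, 33 of 33 runs differed in the same direction, which their selection on these same arrays largely fixed, so a slide effect is not checked by it. The position of Ikzf1 among these probes was not determined, so the runs do not check its copy number. The count was 2 with medians over probes and fell to 14 without Ikzf1+/+ tumour 4. After normexp correction it was 268, with 216 higher and 52 lower in Ikzf1+/- tumours, so most called runs were then higher instead of lower. More runs passed in both directions, and whether the same runs changed direction was not examined.

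The number and extent of copy number changes per tumour were compared between genotypes. Gains were called 39, 8, 9, 19 and 6 times in Ikzf1+/+ tumours 1 to 5, and 1, 5, 1, 1 and 4 times in Ikzf1+/- tumours 1 to 5. The means were 16.2 ± 13.7 against 2.4 ± 1.95 (SD, n = 5 each). The 9 gains of Ikzf1+/+ tumour 3 include separate calls on chromosome 5 starting at 3296249, 3359677, 3459652, 110082126 and 143515888. That chromosome was raised along its length in this tumour. Counted as a single gain, it would leave this tumour no more gains than Ikzf1+/- tumour 2. The full separation of the genotypes in gain counts thus depends on these separate calls, and the test was not run on such counts. Losses were called 6, 6, 4, 4 and 18 times in Ikzf1+/+ and 0, 7, 0, 4 and 9 times in Ikzf1+/- tumours, or 7.6 ± 5.90 against 4 ± 4.06. Calls shared by 8 or more arrays were left out. Among them were short chromosome 12 losses of Ikzf1+/- tumours 3 and 4, which had 1 and 5 losses with them, while longer losses there were kept. Gained DNA summed to 34.3 ± 64.6 Mb in Ikzf1+/+ and 0.350 ± 0.357 Mb in Ikzf1+/- tumours, with 149 Mb in Ikzf1+/+ tumour 3. Long segments just under the threshold were not counted, among them +0.28 on chromosome 14 (3882 probes) and +0.27 and +0.28 over 29.6 and 12.7 Mb of chromosome 19 in Ikzf1+/- tumour 5, which counted 0.870 Mb. Chromosome 5 of Ikzf1+/+ tumour 5, with a median of +0.21, was not counted either. Lost DNA summed to 5.16 ± 7.66 and 0.769 ± 0.892 Mb. The 151 calls counted, 93 gains and 58 losses, had a median length of 60.7 kb, and 14 exceeded 1 Mb. The difference in gains, Ikzf1+/- minus Ikzf1+/+, was -13.8 (two-sided exact permutation p = 0.00794, the smallest the design allows, adjusted p = 0.0317 over 4 measures) and that in Mb gained -33.9 (exact p = 0.0238, adjusted p = 0.0476). The differences in losses, -3.6 (exact p = 0.349), and in Mb lost, -4.39 (exact p = 0.151, adjusted p = 0.201), were within the spread between tumours. On the shared slide the Ikzf1+/- tumour minus the Ikzf1+/+ tumour gave -5 gains, -18.5 Mb gained, -18 losses and -18.6 Mb lost. The Mb gained came mostly from 1 chromosome 19 call of Ikzf1+/+ tumour 5 joined across segments below 0.3 to a mean of +0.23. Without joining that tumour had 4.15 Mb gained and Ikzf1+/- tumour 1 had 0.0949 Mb. Without joining, the genotypes differed by -16.4 gains (exact p = 0.00794), -30.9 Mb gained (exact p = 0.0317), -4.6 losses (exact p = 0.246) and -4.36 Mb lost (exact p = 0.143). The difference in gains missed the threshold after normexp correction (-10.2, exact p = 0.0635), with calls at 0.5 (-8.2, exact p = 0.0794) and without Ikzf1+/- tumour 1, 3 or 4 (-13.45, exact p = 0.0556), and was -8.1 without Ikzf1+/+ tumour 1. That in Mb gained was -5.23 without Ikzf1+/+ tumour 3, and missed the threshold without any 1 Ikzf1+/- tumour (exact p from 0.222 to 0.270), after normexp correction (exact p = 0.206) or loess (exact p = 0.0714), and with calls at 0.2 (exact p = 0.183) or 0.5 (exact p = 0.103). The difference in losses passed it after normexp correction (-6.6, exact p = 0.0476), and that in Mb lost after normexp correction (-4.10, exact p = 0.0159), with calls at 0.5 (-1.60, exact p = 0.0238) and without Ikzf1+/+ tumour 3 or 4 (exact p = 0.0476). Without Ikzf1+/+ tumour 5 these differences were -1 losses and -1.02 Mb.

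**Figure D1:**
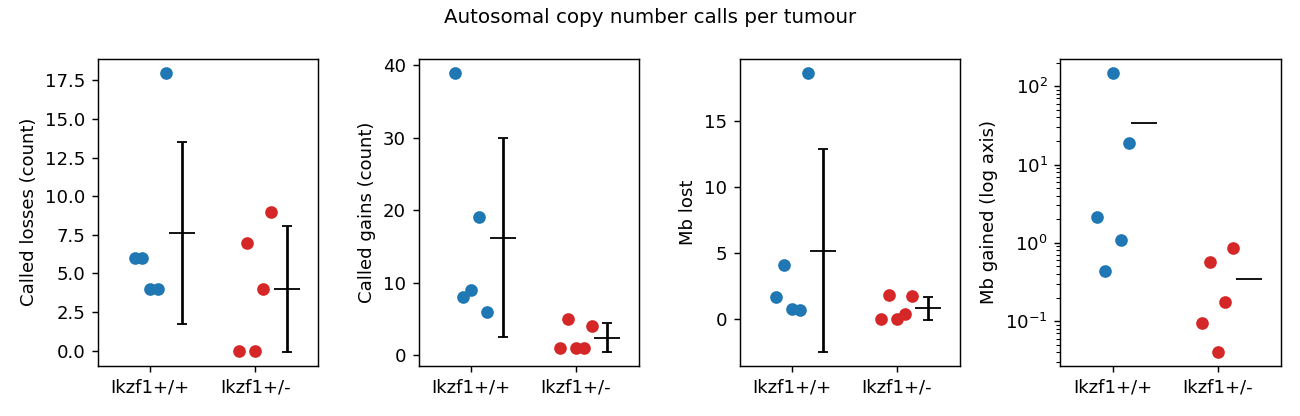
Called autosomal losses and gains (counts), Mb lost and Mb gained (log axis) per tumour; points are tumours, 5 Ikzf1+/+ in blue and 5 Ikzf1+/- in red, horizontal lines are group means and vertical bars ± 1 SD, not drawn on the log axis. Each Ikzf1+/+ tumour had 6 or more gains, and each Ikzf1+/- tumour 5 or fewer.

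The called loss of lowest mean lay on chromosome 4 from 88879097 to 89076517 (mm9), 197 kb with 172 probes, in Ikzf1+/+ tumour 1 at a mean log2 ratio of -3.30 (SD over probes 0.952). Ikzf1+/+ tumour 5 had a shallower loss from 88859687 to 89076517 at -0.59 over 177 probes. Over the shared interval Ikzf1+/- tumours averaged +0.011 ± 0.021 (SD, n = 5) and 0 of them had a loss called. Chromosome 4 carries the cell cycle inhibitor genes Cdkn2a, Cdkn2b and Cdkn2c and the B-cell transcription factor gene Pax5 in the GRCm38 gene table; which genes the interval holds was not determined.

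**Figure D2:**
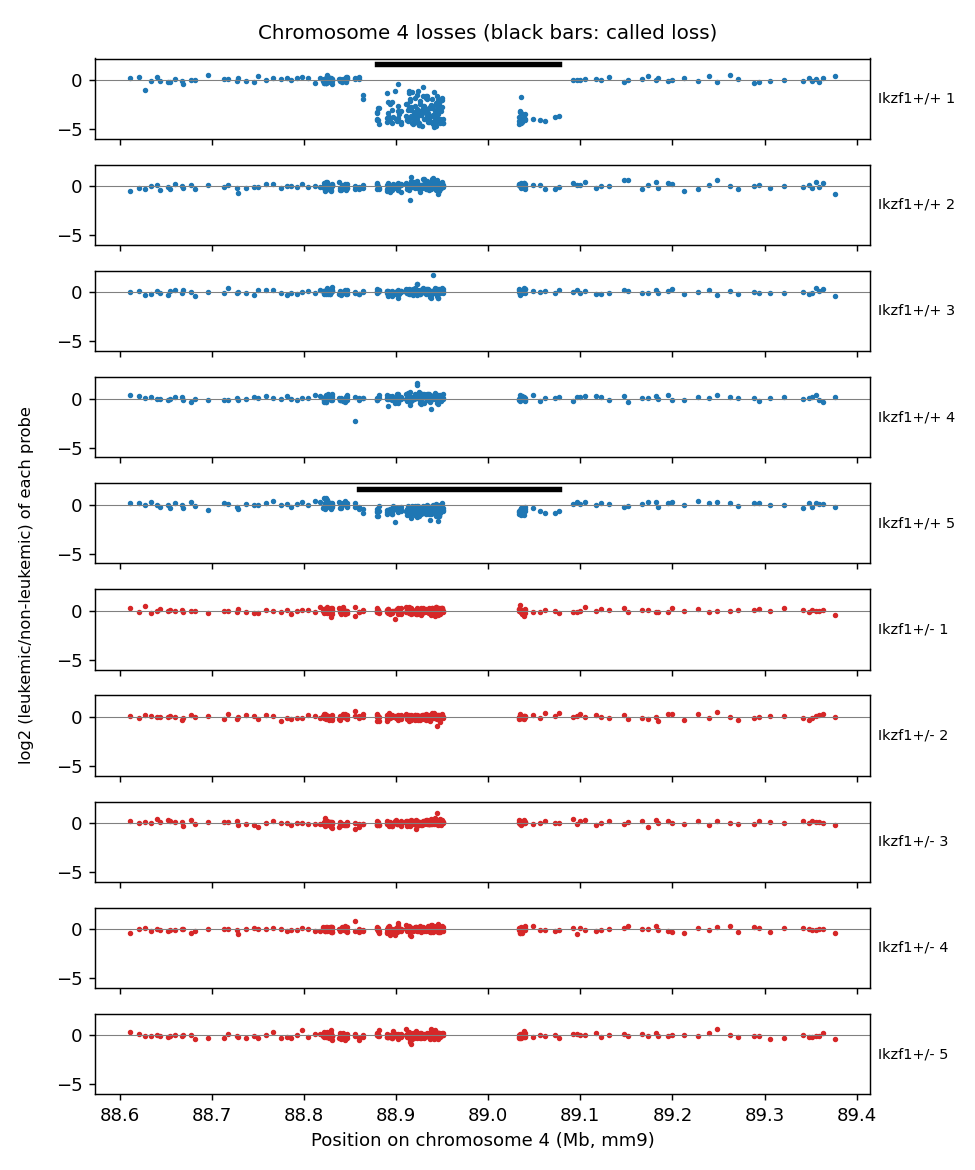
Log2 ratio of leukemic to non-leukemic DNA at each probe (points) by position on chromosome 4 (Mb, mm9), 1 panel per tumour, Ikzf1+/+ in blue and Ikzf1+/- in red, with black bars over called losses. Probes of Ikzf1+/+ tumour 1 average -3.30 between 88879097 and 89076517.

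Losses on chromosome 12, which carries the immunoglobulin heavy chain locus Igh, were called in 9 of 10 tumours, the exception being Ikzf1+/- tumour 1, within 114670169 to 115978441 (1308 kb, 182 probes). The calls shared their proximal end within 13.3 kb, whereas the distal ends spread over 1211 kb and call lengths ran from 96.9 to 1308 kb. Segments below -1 lay in 5 tumours, at -4.20, -3.65 and -1.32 in Ikzf1+/+ tumours 2, 3 and 5 and at -2.85 and -1.18 in Ikzf1+/- tumours 2 and 5. Ikzf1+/+ tumour 4 had no such segment. Its probes starting at 114670169, 114675830 and 114683474 nevertheless lay at -2.31, -4.19 and -4.22, with -0.58 at 114672646, within a segment of mean -0.89. The region averaged -0.59 ± 0.29 in Ikzf1+/+ and -0.24 ± 0.28 in Ikzf1+/- tumours (SD, n = 5 each), a difference of +0.35 within the spread between tumours (two-sided exact permutation p = 0.0952). The called length per tumour was 832 ± 425 and 384 ± 473 kb, with 0 kb for the Ikzf1+/- tumour without a call (n = 5 each, exact permutation p = 0.159). The region was chosen from the calls; without Ikzf1+/- tumour 2 its difference was +0.45 (exact p = 0.0317), and after normexp correction +0.026 (exact p = 0.730).

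**Figure D3:**
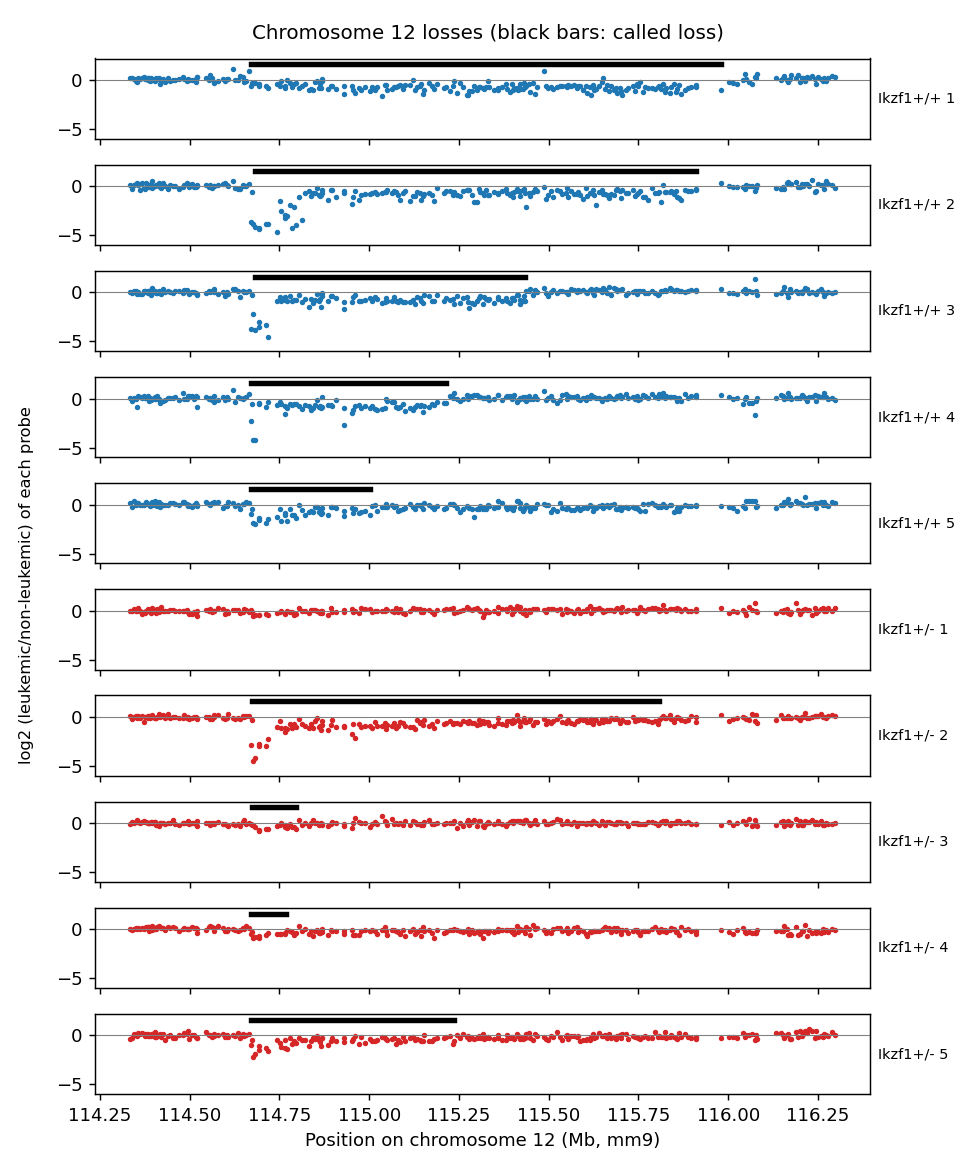
Log2 ratio of leukemic to non-leukemic DNA at each probe (points) by position on chromosome 12 (Mb, mm9), 1 panel per tumour, Ikzf1+/+ in blue and Ikzf1+/- in red, with black bars over called losses. Bars start within 13.3 kb of each other and end over a range of 1211 kb.

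With calls shared by 8 or more arrays left out, regions called in at least 2 tumours numbered 8 losses and 17 gains. Of the losses 2 were called in Ikzf1+/+ tumours alone, 2 in Ikzf1+/- tumours alone and 4 in both. Of the gains 13 were called in Ikzf1+/+ alone, 2 in Ikzf1+/- alone and 2 in both. Tumours without a call can lie short of the threshold of 0.3 in the same direction. On chromosome 4 a gain at 133297679 to 133374043 was called in 5 Ikzf1+/+ tumours and Ikzf1+/- tumour 5, with means of +0.52 ± 0.09 and +0.22 ± 0.11 (SD, n = 5 each). Gains at 44538376 to 44543217 and 35780730 to 35838445 on the same chromosome, and at 41003657 to 41026941 on chromosome 19, were each called in 4 Ikzf1+/+ tumours and 0 Ikzf1+/- tumours, with means of +0.65 against +0.065, +0.41 against +0.23 and +0.77 against +0.12. Chromosome 13 from 61942334 to 62037213 was gained in 4 Ikzf1+/- and 0 Ikzf1+/+ tumours (+0.59 ± 0.25 against -0.14 ± 0.08), and chromosome 9 from 40495947 to 40642551 in 2 Ikzf1+/+ and 1 Ikzf1+/- tumours (+0.34 in both means), or in 4 Ikzf1+/+ and 5 Ikzf1+/- tumours with the shared calls. Gains on chromosome 8 at 125416197 to 125419865, chromosome 16 at 16860895 to 16864189 and chromosome 19 at 45836258 to 45851490 were called in 3 Ikzf1+/+ tumours each. The chromosome 19 count includes the joined call of Ikzf1+/+ tumour 5, whose segment of 6.68 Mb there averaged +0.25, below the call threshold. Over the 5 probes of the named interval alone that tumour averaged +0.69. Ikzf1+/- tumour 5, without a call there, averaged +0.47. A gain on chromosome 10 at 117126240 to 117146475 was called in 2 Ikzf1+/+ tumours. Losses were called on chromosome 11 at 116609271 to 116626075 in 3 Ikzf1+/- tumours (-0.54 ± 0.24, against +0.021 ± 0.13 in Ikzf1+/+). On chromosome 14 at 69876584 to 70082968 they were called in 2 Ikzf1+/- tumours (-0.34, against -0.052 in Ikzf1+/+). At 42523843 to 44430990 they were called in 2 Ikzf1+/+ tumours, but the means were -0.215 in Ikzf1+/+ and -0.205 in Ikzf1+/-. The called Ikzf1+/+ tumours 2 and 5 lay lowest there, at -0.34 and -0.45, and Ikzf1+/+ tumours 1, 3 and 4 at -0.017, -0.25 and -0.018. The Ikzf1+/- tumours lay between -0.28 and -0.12, short of the threshold. The calls in Ikzf1+/+ tumours alone thus do not reflect a difference in group means. Losses on chromosome 4 at 3205206 to 3311575 and chromosome 1 at 90109653 to 90204948 were called in 1 Ikzf1+/+ and 2 Ikzf1+/- tumours. Their means in Ikzf1+/+ and Ikzf1+/- were -0.21 and -0.29 on chromosome 4, and -0.15 and -0.29 on chromosome 1. A loss on chromosome 5 at 3401290 to 3459936 was called in 1 of each (-0.17 and -0.25). Per window, Fisher's exact test found 0 of 132 windows with a loss past adjustment (0 at an unadjusted p under 0.05, smallest exact p = 0.167) and 0 of 1722 with a gain (7 at an unadjusted p under 0.05, smallest exact p = 0.0476).

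Whole chromosomes were compared through their median ratios, for which 3 copies against 2 would give +0.58. Chromosome 5 was gained in Ikzf1+/+ tumour 3 at +0.46 and tumour 5 at +0.21, and chromosome 19 in Ikzf1+/+ tumour 5 at +0.22. Each of 4 parts of the chromosome lay between +0.42 and +0.48 in the first, +0.17 and +0.24 in the second and +0.21 and +0.23 in the third case. Chromosome 19 of Ikzf1+/- tumour 5 had a median of +0.19, short of the threshold of 0.2, from 4 such parts at +0.26, +0.28, +0.22 and -0.026. In the gene table chromosome 5 carries the receptor tyrosine kinase genes Kit and Flt3 and the genes Ptpn11, Sh2b3, Chek2, Nsd2, Auts2 and Magi2, and chromosome 19 the kinase gene Jak2 and the genes Blnk, Pik3ap1 and Prkg1. By list, chromosomes 5 and 19 carried 0 and 1 of 30 B-lineage genes, 4 and 2 of 28 signalling genes, 1 and 0 of 17 chromatin genes, and 2 and 1 of 12 long genes of fragile sites, and chromosome 5 carried 1 of 21 tumour suppressor and cell cycle genes. Of 19 autosomes, 0 differed between genotypes after adjustment by the two-sided exact permutation test (smallest adjusted p = 0.201). Chromosomes 10, 11 and 13 had unadjusted exact p = 0.0238, 0.0317 and 0.0317. At the smallest possible exact p of 0.00794, an autosome that differed alone could not pass adjustment over 19.

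**Figure D4:**
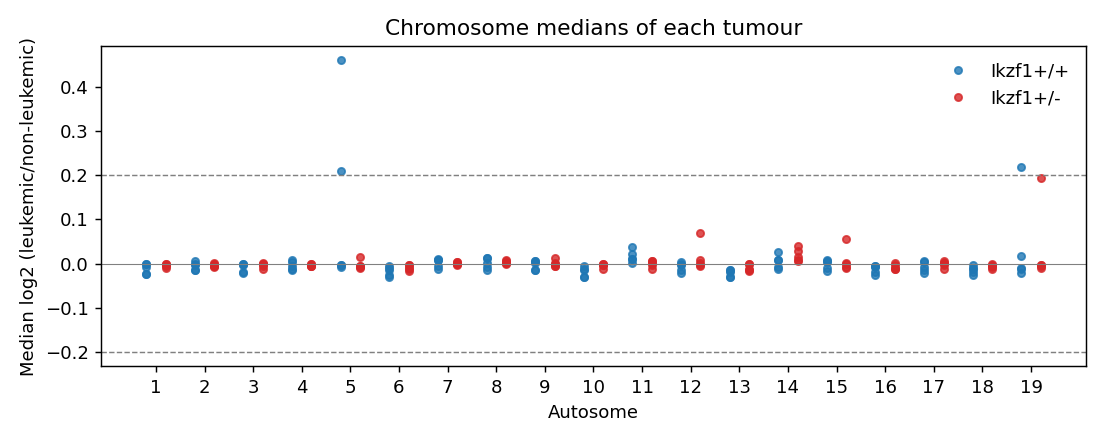
Median log2 ratio of leukemic to non-leukemic DNA of each autosome; each point is 1 tumour, 5 Ikzf1+/+ in blue and 5 Ikzf1+/- in red, and dashed lines mark the call threshold of 0.2 in either direction. Chromosome 5 of Ikzf1+/+ tumours 3 and 5 and chromosome 19 of Ikzf1+/+ tumour 5 lie above the line.

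Windows of 100 kb were compared between genotypes to find smaller differences. Of 23425 windows, 5 differed in limma after adjustment, 4 higher and 1 lower in Ikzf1+/- tumours. In each of these 5 of 5 Ikzf1+/- tumours lay on that side of all Ikzf1+/+ tumours, which the selection of the windows on these same arrays largely fixed. The window starting at 121800001 on chromosome 11 had -0.40 ± 0.07 in Ikzf1+/+ and +0.32 ± 0.16 in Ikzf1+/- tumours (SD, n = 5 each, difference +0.71, limma adjusted p = 0.00198, 3 probes). The window at 61900001 on chromosome 13 differed by +0.57 (limma adjusted p = 0.0448), that at 50400001 on chromosome 1 by +0.20 (limma adjusted p = 0.0492), that at 7500001 on chromosome 11 by +0.16 (limma adjusted p = 0.0448) and that at 52500001 on chromosome 5 by -0.33 (limma adjusted p = 0.0448). On the shared slide the 5 differences were +1.02, +0.51, +0.21, +0.14 and -0.30, with signs fixed by the selection of the windows on these same arrays. The count was 0 with medians over probes or at least 10 probes per window, and 71 after normexp correction. It was 25 without Ikzf1+/+ tumour 3, with 9 higher and 16 lower in Ikzf1+/- tumours, against 1 or 2 without any other tumour. The chromosome 1 window turned to -0.048 after normexp correction (limma adjusted p = 0.458).

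Tumour DNA of both genotypes was also set against the non-leukemic DNA. Tumour DNA carried Cy5 on every array, so this test does not separate tumour changes from a dye effect shared by all arrays. It also leaves out the spread of the non-leukemic DNA where arrays shared it, which the labels did not state. The windows below are therefore not all tumour copy number changes. In limma 1837 windows were higher and 3084 lower after adjustment, with a median absolute ratio of 0.070; 823 reached 0.1 and 12 reached 0.3. The highest lay at 40500001 on chromosome 9 (+0.36, limma adjusted p = 4.69e-05, above 0 in 10 of 10 tumours), 133300001 on chromosome 4 (+0.36, 10 of 10), 41000001 on chromosome 19 (+0.27, 8 of 10) and 111400001 on chromosome 7 (+0.24, 9 of 10), followed by 35800001 on chromosome 4, 72700001 on chromosome 8, 87700001 and 29100001 on chromosome 17, 52700001 on chromosome 14 and 119900001 on chromosome 5, between +0.19 and +0.21. The lowest lay at 114700001 on chromosome 12, within the region of losses described for that chromosome (-0.995, limma adjusted p = 0.00770, 10 of 10 tumours), at 24400001 on chromosome 12 (-0.35, 9 of 10), 7800001 on chromosome 7 (-0.33, 10 of 10) and 143100001 on chromosome 4 (-0.29, 9 of 10). Windows at 44400001 on chromosome 14, 13100001 and 62200001 on chromosome 13, 3200001 on chromosome 4, and 181700001 and 175400001 on chromosome 2 lay between -0.28 and -0.24. After normexp correction the split was 3302 higher and 3395 lower, and the chromosome 7 window at 111400001 had -0.0018 with the median over probes (limma adjusted p = 0.966).

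Sex chromosomes were kept apart because the sex of the animals was not labelled. The X median was +0.91 ± 0.04 in Ikzf1+/+ and +0.11 ± 0.02 in Ikzf1+/- tumours, and the Y median -2.57 ± 0.22 and +0.074 ± 0.018 (SD, n = 5 each, two-sided exact permutation p = 0.00794 for X and for Y). A single X against 2 would give a log2 difference of 1. With X and Y windows included, the limma comparison of genotypes called 1986 windows.

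**Figure D5:**
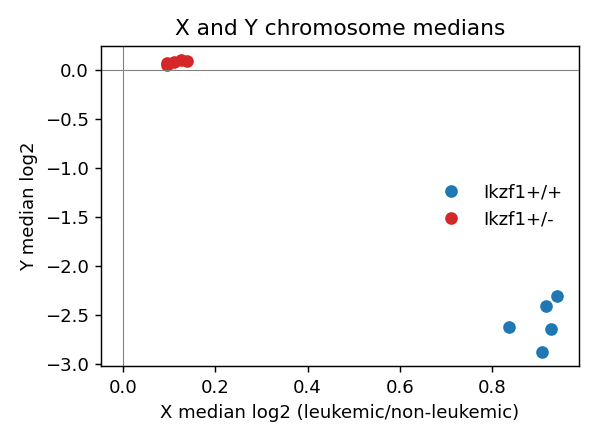
Median log2 ratio of leukemic to non-leukemic DNA over X probes (horizontal) and Y probes (vertical); each point is 1 tumour, 5 Ikzf1+/+ in blue and 5 Ikzf1+/- in red, with grey lines at 0. The Ikzf1+/+ tumours average +0.91 on X and -2.57 on Y.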

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

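The tests of random noise, dye bias, both chromosome 12 explanations, the X and Y ratios and the splits of the windows were chosen after the results had been seen; that of probes sharing X sequence and the splits of the chromosome 11 runs were set beforehand.

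X and Y ratios separated the genotypes without overlap, the difference Ikzf1+/- minus Ikzf1+/+ being -0.79 on X and +2.64 on Y. Loss of the Y chromosome in the Ikzf1+/+ tumours alone would leave X near 0, whereas their mean X median was +0.91. A mean Y median of -2.57 together with that X value is consistent with leukemic and non-leukemic DNA of different sex on all 5 Ikzf1+/+ arrays. Whether the animals or the reference differed was not tested, and such a mismatch would coincide with genotype in every comparison.

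Ikzf1+/+ tumours had more gains, by -13.8 calls and -33.9 Mb for Ikzf1+/- minus Ikzf1+/+, or -8.1 calls without Ikzf1+/+ tumour 1, which held 39 of the 81 gains and 635 segments, and -5.23 Mb without Ikzf1+/+ tumour 3. Random noise of single arrays is argued against, because at the 77 gains under 1 Mb the other Ikzf1+/+ arrays lay above the Ikzf1+/- arrays by a median of 0.204 (quartiles 0.130 and 0.350), and at 73 of the 77 they lay above. The 77 are calls and not separate places. A place called in several Ikzf1+/+ arrays enters once for each of them, so these values count some places repeatedly. The difference in gains was -14.2 after loess. That loess was run on processed signals from a protocol whose name already states lowess, so it could change little. A dye bias that depends on signal is therefore not checked by it. A sex mismatch at probes that also bind X sequence could add such gains; at 46.8% of them, between the bounds set beforehand of 50% and 20%, each other Ikzf1+/+ array reached 0.15, so this cannot be told apart from other sources shared by these arrays. The lower Cy5 signal of the Ikzf1+/+ arrays, waves along the genome that were seen in Ikzf1+/+ tumour 1 and for which no GC correction was run, and a biological difference between genotypes stay open as well, all untested.

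Both differences in gains missed the threshold after normexp correction (-10.2 calls, exact p = 0.0635, and -41.6 Mb, exact p = 0.206). They also missed it with calls at 0.5 (-8.2 calls, exact p = 0.0794, and -6.71 Mb, exact p = 0.103). Mb gained also missed it after loess (-30.3, exact p = 0.0714) and with calls at 0.2 (-55.4, exact p = 0.183).

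Losses within a region of 1308 kb on chromosome 12 were called in 9 of 10 tumours. A copy number difference of strain or reference DNA with fixed ends, shared by all arrays, is argued against by the SD of 464 kb among the distal ends. Call ends also depend on the depth of a loss against the threshold. The stretch from 114683474 to 114767078 averaged -0.30 even in Ikzf1+/- tumour 1, which had no call. The B-cell reference may itself be rearranged at Igh, without fixed ends, and the distal ends do not check this. An SD of 5.65 kb among the proximal ends beside that is consistent with tumour deletions having 1 shared and 1 varying end, as V(D)J joining leaves at Igh. This remains a hypothesis, since the region was found in the same data and its genes were not determined.

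The 5 windows that differed between genotypes were matched by 1 of 100 splits of the arrays drawn from 126, the real one, and the highest other count was 0; for the 33 chromosome 11 runs it was also 1 of 100, with a highest other count of 1. Counts this high were thus rare among the 100 splits, which does not exclude a random grouping of the arrays. Mixed splits also hold any difference between the real groups as spread within their groups, which lowers their counts. Slide and the X and Y difference follow the real split almost or fully.

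Of 52 sets of 5 values examined, 9 held a tumour far from the others. The sets depend on each other, as losses and Mb lost of the same tumours do, so no chance rate is set beside them. Ikzf1+/+ tumour 5 had 18 losses, 18.6 Mb lost and a chromosome 19 median of +0.22, and Ikzf1+/+ tumour 3 had 149 Mb gained. Ikzf1+/- tumour 5 stood apart on chromosome 19 at +0.19, chromosome 5 at +0.015 and chromosome 10 at -0.013, Ikzf1+/- tumour 4 on chromosome 12 at +0.069 and Ikzf1+/- tumour 2 on chromosome 15 at +0.056.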

How the results depend on the processing

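Calls left unjoined, calls without the chromosome 12 region and the chromosome 12 region itself were chosen after the data had been seen; the other alternatives were planned. The causes of the changes below were not tested. After normexp correction the difference Ikzf1+/- minus Ikzf1+/+ was -6.6 losses (exact p = 0.0476), -4.10 Mb lost (exact p = 0.0159), -10.2 gains (exact p = 0.0635) and -41.6 Mb gained (exact p = 0.206). With that correction 71 windows and 268 chromosome 11 runs differed, and 216 of the runs were higher and 52 lower in Ikzf1+/- tumours. With loess the Mb gained differed by -30.3 (exact p = 0.0714), and 1 window and 21 runs differed. Calls at 0.2 gave -55.4 Mb gained (exact p = 0.183), and calls at 0.5 gave -8.2 gains (exact p = 0.0794), -1.60 Mb lost (exact p = 0.0238) and -6.71 Mb gained (exact p = 0.103). Medians over probes left 0 windows (3019 at an unadjusted p under 0.05 in limma), 2 runs and 2964 windows between tumour and non-leukemic DNA. At least 10 probes per window left 0 windows (3124 unadjusted), X and Y included gave 1986, and slide as a random block gave 54 runs. The chromosome 1 window at 50400001 reversed to -0.048 after normexp, and the chromosome 7 window at 111400001 to -0.0018 with medians over probes. Of the other alternatives for named windows, 37 left the differences between genotypes on their side of the threshold and 52 did not; 358 did so for tumour against non-leukemic DNA.

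Replicate numbers did not pair the samples: deviations of equal numbers correlated at 0.044, 0.045, -0.018, 0.0031 and 0.20, and 2 of 5 Ikzf1+/+ arrays correlated best with their own number. With the replicate block, where the smallest exact p is 0.0625, the gains differed by -13.8 (exact p = 0.0625) and Mb gained by -33.9 (exact p = 0.125), with 1 window, 25 runs and 4009 windows of tumour against non-leukemic DNA.

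Leaving out each tumour in turn gave -4.85 to -1 losses, -16.35 to -8.1 gains, -5.51 to -1.02 Mb lost, -42.4 to -5.23 Mb gained, +0.24 to +0.45 on chromosome 12, 1 to 25 windows, 14 to 39 runs, 3293 to 5353 windows of tumour against non-leukemic DNA, and 0 to 0 autosomes and windows of more frequent loss. An autosome or window that differed alone could not pass adjustment with this number of arrays, so the 0 counts say little about stability. Gains fell to -8.1 without Ikzf1+/+ tumour 1 and missed the threshold without Ikzf1+/- tumour 1, 3 or 4 (-13.45, exact p = 0.0556). Mb gained was -5.23 without Ikzf1+/+ tumour 3 and missed the threshold without each Ikzf1+/- tumour (exact p from 0.222 to 0.270). Mb lost passed it without Ikzf1+/+ tumour 3 or 4 (exact p = 0.0476), and chromosome 12 without Ikzf1+/- tumour 2 (exact p = 0.0317). Losses, -1 at the least, and Mb lost, -1.02 at the least, were closest to 0 without Ikzf1+/+ tumour 5. Windows numbered 25 without Ikzf1+/+ tumour 3, 2 without Ikzf1+/- tumour 2 and 1 without each other tumour; runs numbered 17, 14, 19, 17, 18 and 17 without Ikzf1+/+ tumours 1 and 4 and Ikzf1+/- tumours 1, 2, 3 and 4. A GC correction, the gene-level Ikzf1 value, receptor loci and list genes lost were not run. At the noise of Ikzf1+/+ tumour 1, 15% of simulated 10-probe gains of 0.4 were recovered, against 75% at that of Ikzf1+/- tumour 3; the effect of Cy5 signal on calls was not tested.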

Other observations

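The segments and intervals described here, and the runs over all autosomes, were examined after the data had been seen; segments of at least 3 Mb were taken from an absolute mean of 0.15, a threshold raised after a lower one had been tried.

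Ikzf1+/- tumour 5 carried gains of parts of chromosomes that missed the call threshold of 0.3. Chromosome 14 was raised from 95136374 to 125170673 (mm9) at +0.28 over 3882 probes. Chromosome 19 was raised from 3147156 to 32751358 at +0.27 and from 33334872 to 46021876 at +0.28, on either side of a gain called from 32751679 to 33325622 at +0.35, while its distal part from 50380884 lay at -0.026. The same tumour had a loss on chromosome 11 from 44369539 to 44703340 at -0.41 over 1030 probes, and Ikzf1+/+ tumour 5 had a gain at 44718315 to 44800797 at +0.32 over 265 probes. In the GRCm38 table chromosome 11 carries Ikzf1, Ikzf3, Ebf1, Trp53 and Nf1; which genes these intervals hold was not determined.

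Runs of 5 probes that differed between genotypes were not confined to chromosome 11. Over all autosomes limma called 15 of 76418 runs higher (0.020%) and 66 lower (0.086%) in Ikzf1+/- tumours. Chromosome 11 had 3 higher (0.063%) and 8 lower (0.17%), and chromosome 5 had 0 higher and 13 lower (0.28%). Fitted and adjusted over all autosomes, fewer chromosome 11 runs thus passed than the 8 higher and 25 lower found with that chromosome alone. The 3 runs of smallest adjusted p among those higher were on chromosomes 11, 11 and 3.

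Log ratios over windows correlated at a median r of 0.34 among Ikzf1+/+ arrays (0.18 to 0.65), 0.27 among Ikzf1+/- arrays (0.21 to 0.32) and 0.18 between genotypes (0.070 to 0.37). These correlations are across windows, which are not independent replicates.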
